A study of Mus musculus with 2 samples.

How the data were processed

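Droplet-based single-cell RNA sequencing was available for 2 libraries of mouse embryonic kidney cells at embryonic day 16.5, with 1 library per genotype. Per the labels, one library holds wild-type Six2-positive nephron progenitor cells and the other holds nephron progenitor cells of a conditional Hdac1 and Hdac2 mutant, both on a C57BL/6 background. The labels do not say how many embryos were pooled, which exons were deleted, which driver deleted them, or whether the mutant cells passed the same gate on Six2 as the wild-type cells. Per the labels, libraries were made with 10x Genomics v2 chemistry and sequenced on a NextSeq500. The submitters' processing notes name Cell Ranger 2.1.0, Seurat 4.1.1 and the mouse genome build mm10, without saying which step each served. The counting settings, including the use of strand, are not given in the sources used here.

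The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized, in matrices of 27998 genes that the authors had already limited to called cell barcodes. Gene symbols and identifiers were used as the files give them. Of these identifiers, 27645 are in the GENCODE M21 annotation of GRCm38, the build that mm10 denotes, and coordinates come from that annotation. Symbols shared by several identifiers, 121 genes in all, were kept apart.

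Cells with at least 500 detected genes and under 10% mitochondrial counts were kept. This removed 19 wild-type and 35 mutant barcodes. Doublets were scored within each library by the share of simulated doublets, made by adding the counts of random pairs of cells, among each cell's nearest neighbours, with code written for this work after the idea of Scrublet. An expected doublet share of 0.8% per 1000 cells was assumed, and the highest-scoring 883 wild-type and 413 mutant cells were removed. The quality filter, the doublet share and the steps described from here to the gene lists were set before the data were examined, except where stated.

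Counts of the kept cells were scaled per cell, log-transformed and reduced to 2000 variable genes and 30 principal components. Both libraries were clustered together, without integration, by the Leiden method at resolution 1 on a shared nearest neighbour graph of 20 neighbours, which gave 22 clusters. Hdac1, Hdac2, Xist, Y-linked, mitochondrial, ribosomal protein and haemoglobin genes did not enter the clustering. Clusters were called "X-like" from 12 marker lists fixed in advance. The thresholds of that step were set after seeing the data. Any class but nephron progenitor-like and early committed nephron-like needed at least 3 markers at 10 CPM (the counts of a gene scaled to a common total) or more. These markers had to stand at 4 times the median cluster or more, with at least 2 markers among the 10 leading genes. A nephron progenitor-like cluster needed at least 7 of 12 progenitor markers above the clusters of those other classes. An early committed nephron-like cluster needed a gain in at least 4 of 12 early markers over the progenitor-like baseline. Clusters that met no rule, or in which haemoglobin made up 1% or more of the counts, stayed unnamed.

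With 1 library per genotype no test between genotypes was possible, and cells were not used as replicates. For each class, raw counts were summed over the cells of a library and given as CPM of the class total. A comparison is the log2 ratio of mutant to wild type, with 0.5 added to each sum, and an exact Poisson (conditional binomial) 95% interval. Shares of cells carry exact Clopper-Pearson 95% intervals. All intervals and limits cover counting error only, except the order-statistic intervals of medians over genes. Those reflect the spread over the genes, taken as independent. No interval covers variation between embryos or libraries. A count of 0 was bounded at 3 counts.

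The rule for the genes named in nephron progenitor-like cells took Hdac1, Hdac2, the 12 highest and the 12 lowest log2 ratios among genes with at least 50 CPM in a library and at least 30 summed counts, and from each gene list up to 4 measured members with the largest absolute ratio. In every other class with at least 100 cells in both libraries it took the 4 highest and the 4 lowest. Xist, Tsix, Y-linked, mitochondrial and haemoglobin genes and genes with clone-style names were not ranked. Fewer than 4 members were taken from some lists, to limit the number of genes described. Of the 12 highest genes 1 is not reported here, and neither are the values of the nephron segment list.

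The 21 gene lists were the HDAC family, subunits of the NuRD, Sin3 and CoREST complexes, nephron progenitor regulators, early nephron differentiation and Wnt targets, nephron segment genes, p53 targets, CDK inhibitors, S phase, G2/M phase, apoptosis, neuronal, germline, imprinted and Hox genes, glycolysis, oxidative phosphorylation, dissociation stress, linker histones and high-mobility group proteins, stromal and extracellular matrix genes, muscle and skeletal lineage genes, and genes that show the sex of the embryos. Members with at least 10 CPM in either library counted as measured. For each list the median log2 ratio is given with its order-statistic interval and with its percentile among 10000 random lists of the same size matched on mean expression. The percentile describes these 2 libraries and is not a test.

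Shares of cells with a UMI of a gene were compared after thinning each cell to 2000 UMIs, and also at 1000 UMIs and without thinning. Cells were called female when they held a UMI of Xist and none of Ddx3y, Eif2s3y, Kdm5d or Uty, and male in the reverse case.

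The ratio step was tested on simulated data for the comparison of nephron progenitor-like cells, with 2601 genes drawn at the wild-type means and 50 genes at each true log2 change of -2, -1, 1 and 2. The medians recovered were -2.07, -1.07, 0.92 and 1.92, and -0.07 for unchanged genes, the common offset being the shift of the totals. The intervals held the true value in 94% to 100% of the genes at each size of change. The simulated sums were Poisson draws without variation between cells, embryos or libraries. This step therefore checks the calculation only, not how well the intervals hold for such variation.

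Alternatives covered the cell filter, doublet removal, Leiden resolutions 0.5 and 2, centring genes within each library, clustering wild-type cells alone and assigning each mutant cell to the clusters of its 20 nearest wild-type neighbours, other scalings, equal weight for every cell, and other minimum levels for list members. Added after seeing the data, ratios were also given relative to stroma-like cells and to cluster 13, as the difference of the log2 ratios, with list members at 20 CPM or more there in either library. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.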

Results

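The study compared nephron progenitors of wild-type mouse kidneys with nephron progenitors labelled as conditional Hdac1 and Hdac2 mutants at E16.5. Nephron progenitors are the Six2-expressing cap mesenchyme cells that renew themselves and give rise to the nephron epithelium. The wild-type library held 10524 barcodes and 54823800 UMIs, with a median of 4397 UMIs per barcode. The mutant library held 7221 barcodes and 59837054 UMIs, with a median of 7497. After filtering, 9622 wild-type and 6773 mutant cells remained. There were no replicates, so every difference described here is a difference between these 2 libraries.

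Hdac1 and Hdac2 encode histone deacetylases that act as catalytic subunits of the NuRD, Sin3 and CoREST complexes. In nephron progenitor-like cells Hdac1 stood at 75.7 CPM in the wild-type library and at 15.1 CPM in the mutant library, 5.0-fold lower (log2 ratio -2.32, 95% interval -2.47 to -2.18). Hdac2 was less far apart, at 290 and 210 CPM (log2 ratio -0.46, interval -0.51 to -0.42). Over all kept cells the log2 ratios were -1.95 for Hdac1 and -0.54 for Hdac2. In early committed nephron-like cells Hdac1 was also lower, at 92.7 CPM in wild type and 15.3 CPM in the mutant.

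Hdac1 was not low in every class of the mutant library. Mutant stroma-like cells held it at 60.8 CPM, against 59.4 CPM in wild-type stroma-like cells, and mutant ureteric epithelium-like and endothelium-like cells held it at 108 and 63.0 CPM. Mutant proximal tubule-like and leukocyte-like cells held less, at 33.9 and 25.7 CPM. Hdac2 was lower in mutant stroma-like cells as well, at 134 against 269 CPM. Relative to stroma-like cells the Hdac2 ratio of nephron progenitor-like cells was 0.54 (interval 0.28 to 0.79), and relative to cluster 13, the stroma-like cluster with cells of both libraries, 0.30 (-0.07 to 0.66). In nephron progenitor-like cells thinned to 2000 UMIs, Hdac1 was detected in 13.3% of wild-type and 2.91% of mutant cells, and in 28.0% and 10.4% without thinning. Hdac2 was detected in 41.2% and 34.0% of thinned cells, whereas without thinning the order was the opposite, 67.3% and 76.1%. Thinning left out 47 wild-type and 0 mutant cells of this class, whose median depths were 4122 and 6812 UMIs. Hdac1 lies on chromosome 4 at 129516104 to 129542713 on the minus strand, and Hdac2 on chromosome 10 at 36974544 to 37001889 on the plus strand (GRCm38). The libraries count transcript 3' ends, and the labels do not say which exons were removed, so a tag outside the deleted part would remain and the Hdac2 level checks nothing about the deletion.

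**Figure D1:**
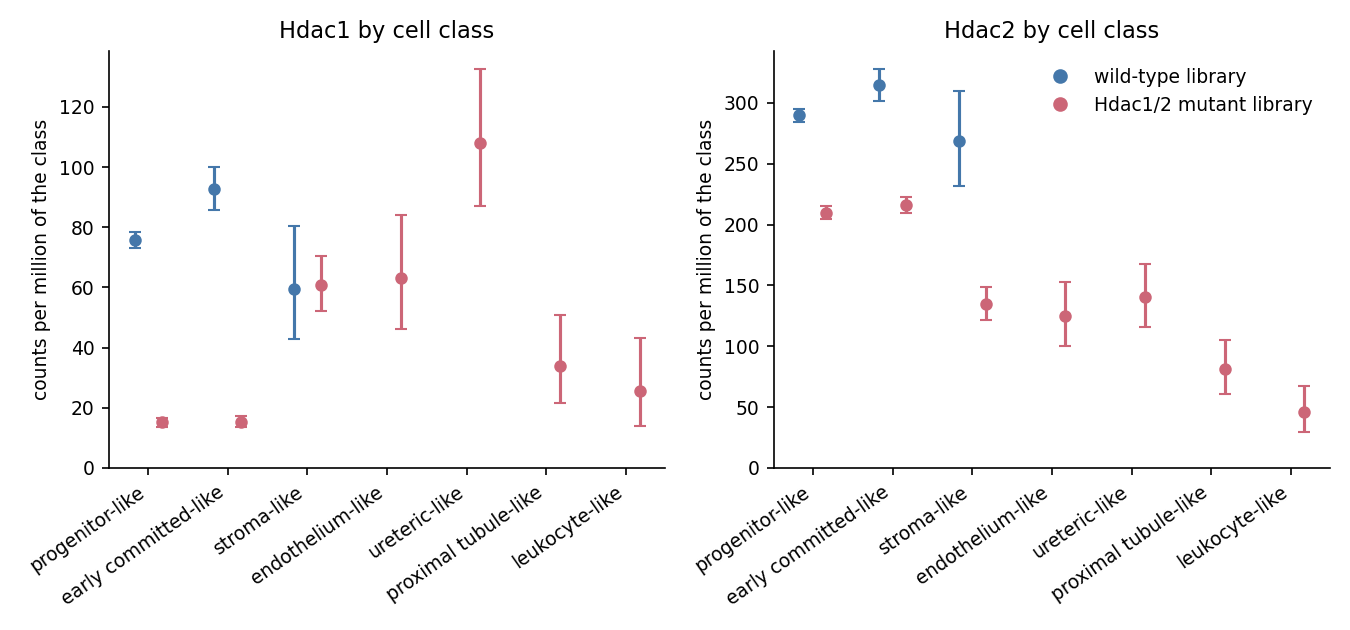
Levels of Hdac1 (left) and Hdac2 (right) in CPM of each cell class, in the wild-type library (blue) and the mutant library (red), with exact Poisson 95% intervals. Hdac1 stands at 15.1 CPM in mutant progenitor-like cells and at 60.8 CPM in mutant stroma-like cells, and wild-type classes with fewer than 10 cells are not drawn.

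Nephron progenitor-like cells made up 85% (84.3 to 85.7) of the wild-type and 55.3% (54.1 to 56.5) of the mutant library. Early committed nephron-like cells made up 13.6% and 32.4%. They were called from a gain in at least 4 of 12 early markers. These are genes of the renal vesicle and pretubular aggregate such as Wnt4, Lhx1 and Jag1, and clusters of the class differed in them. Cells outside both nephron classes made up 1.41% of the wild-type and 12.3% of the mutant library. These were mainly stroma-like cells, at 1.32% and 6.69%, together with leukocyte-like cells at 0.0520% and 1.12% and ureteric epithelium-like cells at 0.0416% and 1.12%. Endothelium-like cells (0.856%) and proximal tubule-like cells (0.901%) were found in the mutant library, against 0 of 9622 wild-type cells, which allows a share of up to 0.0312%. Unnamed clusters held 0 wild-type cells and 1.58% of the mutant cells. Of these, 74 mutant cells were in cluster 17, which had 7 progenitor markers but 2.68% haemoglobin counts, held by 4 cells. They count among the cells outside both nephron classes. A sort on Six2 sets such shares, and the gate of the mutant library is not stated.

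The nephron classes rested on clusters that came almost wholly from a single library. Progenitor-like cells were in clusters 0, 2, 5, 6, 9, 11 and 14 in wild type and mainly in clusters 1 and 4 in the mutant. Early committed nephron-like cells were in clusters 8 and 10 in wild type and 3 and 7 in the mutant. This class was mixed. Of its 1307 wild-type cells 842 were in cluster 8, with Lhx1 at 9.46, Jag1 at 15.1 and Wnt4 at 188.5 CPM. Cluster 10 held these genes at 391, 235 and 242 CPM. The progenitor-like clusters 5 and 11 of wild type held more Jag1 than cluster 8, at 36.3 and 51.6 CPM, but less Lhx1 and Wnt4. In the mutant, Lhx1 stood at 76.3 CPM in cluster 3 and at 25.1 CPM in cluster 7. A cluster mostly of 1 library may be that library rather than a cell type. When mutant cells were assigned to wild-type clusters, the progenitor-like shares were 81.1% and 77.4% and the early committed shares 17.6% and 15.1%, so the order of the early committed shares was reversed. That setting had no endothelium-, ureteric epithelium- or proximal tubule-like class and no unnamed cells. Mutant cells of these groups therefore entered the remaining classes. It also called 10 mutant cells leukocyte-like, against 76 in the main setting. At Leiden resolution 2 the early committed shares were 32.7% and 31.6%.

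**Figure D2:**
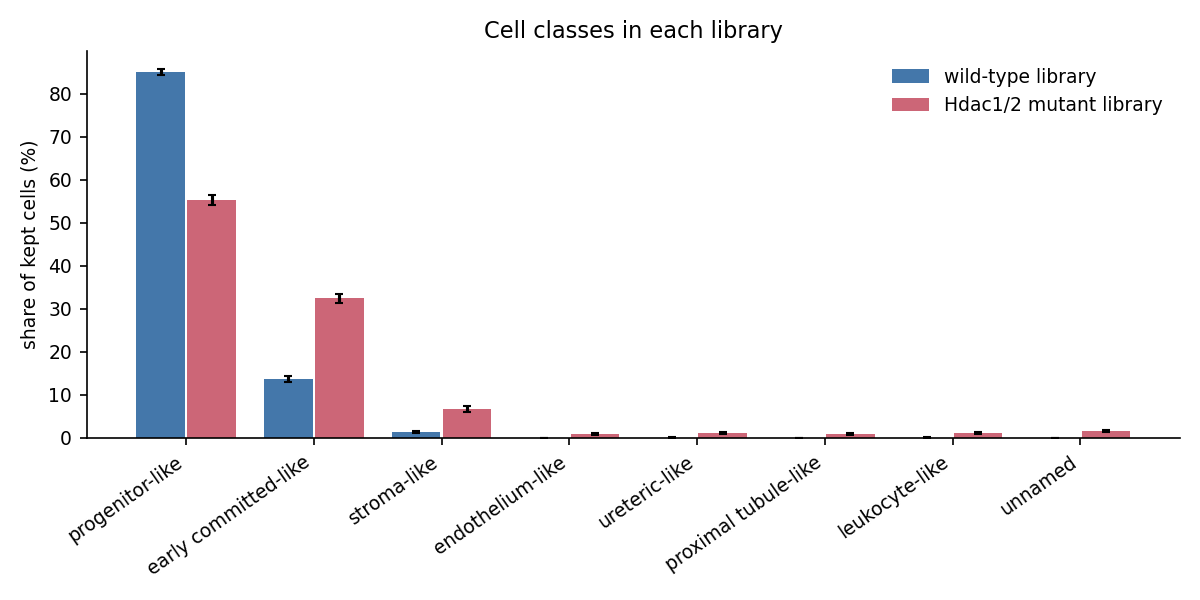
Share of kept cells in each named class, in percent, for the wild-type library (blue, 9622 cells) and the mutant library (red, 6773 cells), with exact binomial 95% intervals. Progenitor-like cells account for 85% and 55.3%, and cells outside the nephron classes for 1.41% and 12.3%.

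Within nephron progenitor-like cells, Srsf2 and Jund had the lowest ratios of mutant to wild type. Srsf2, a splicing factor, stood at 1077 CPM in wild type and 42.4 CPM in the mutant (log2 ratio -4.67, interval -4.75 to -4.58). Jund, an AP-1 transcription factor, stood at 384 and 17.3 CPM (-4.47, -4.60 to -4.34). The other 10 lowest genes were Frat2, a Wnt pathway component (-4.04), Akirin2 (-3.90), Lhfp (-3.84), Ptms (-3.83), Ptov1 (-3.76), Tmem165 (-3.57), Gxylt2 (-3.46), the RNA export adaptor gene Alyref (-3.44), the linker histone gene H1fx (-3.32) and the insulin-like growth factor binding protein gene Igfbp5 (-3.29). Among the 12 highest genes, the carboxypeptidase gene Cpa1 stood at 0.575 CPM in wild type and 51.4 CPM in the mutant (6.45, interval 5.88 to 7.16). Also among the highest were the heat shock gene Hspa1a (5.64), the class I major histocompatibility gene H2-D1 (5.43), Nrsn1 (4.58), the adaptor gene Skap1 (4.45), the imprinted noncoding RNA Meg3 (4.26), the tubulin gene Tubb6 (3.79), Tagln2 (3.62), the transcription factor gene Stat3 (3.47), the noncoding RNA Neat1 (3.31) and Vat1 (3.29).

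The low genes were mostly low in stroma-like cells as well, where Hdac1 stood near its wild-type level and Hdac2 was lower (-0.76 in cluster 13). Of the 12 lowest genes, 10 had a log2 ratio under -1 in stroma-like cells too, in the class as a whole and in cluster 13, a stroma-like cluster with cells of both libraries. Srsf2 stood there at 929 CPM in wild type and 79.2 CPM in the mutant. The exceptions were Lhfp (-0.75) and Igfbp5 (0.16). The cells of cluster 13 also differed in transcripts of other lineages, with Six2 at 40.1 and 3.52 CPM, Eya1 at 93.0 and 7.04 CPM and Uncx at 32.9 and 0 CPM in wild type and mutant. The name of this cluster depended on the settings. With the stricter cell filter 105 of the 106 wild-type stroma-like cells that passed it, and without doublet removal 126 of 127, lay in a cluster that the naming rules called early committed nephron-like. In those clusters 10 of the 12 lowest genes had a log2 ratio under -1. They held 174 and 199 mutant cells, against 84 in cluster 13, and bore a nephron name. These 2 settings therefore cannot show low ratios in stroma-like cells. Most of the highest genes were shared with stroma-like cells too. The 12 highest had a median log2 ratio of 2.33 in cluster 13, with H2-D1 (5.72), Hspa1a (5.46), Stat3 (4.72), Meg3 (3.22), Tubb6 (2.41) and Vat1 (2.26) among them. In the stroma-like class 8 of the 12 had a ratio over 1, including Cpa1, which rests there on 9 mutant counts against 0. Across 2992 genes with at least 20 CPM in both libraries in cluster 13, the log2 ratios of the progenitor-like class and of cluster 13 had a Pearson r of 0.74, and genes are not independent replicates. With the wild-type progenitor profile taken off the wild-type cells of cluster 13 at 51.6%, r was 0.60 over the 2798 genes with at least 20 CPM left. Cpa1, Nrsn1 and Skap1 were singled out after the values were seen. They were chosen for mutant nephron progenitor-like levels at least 4 times those of every named mutant class outside both nephron classes. With mutant cells assigned to wild-type clusters, a setting in which no cluster was defined by mutant cells, their log2 ratios were 5.95, 4.15 and 4.1. Hspa1a differed within the mutant library, at 144 CPM in male and 3.03 CPM in female progenitor-like cells, and among female cells alone its log2 ratio between libraries was 0.94.

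**Figure D3:**
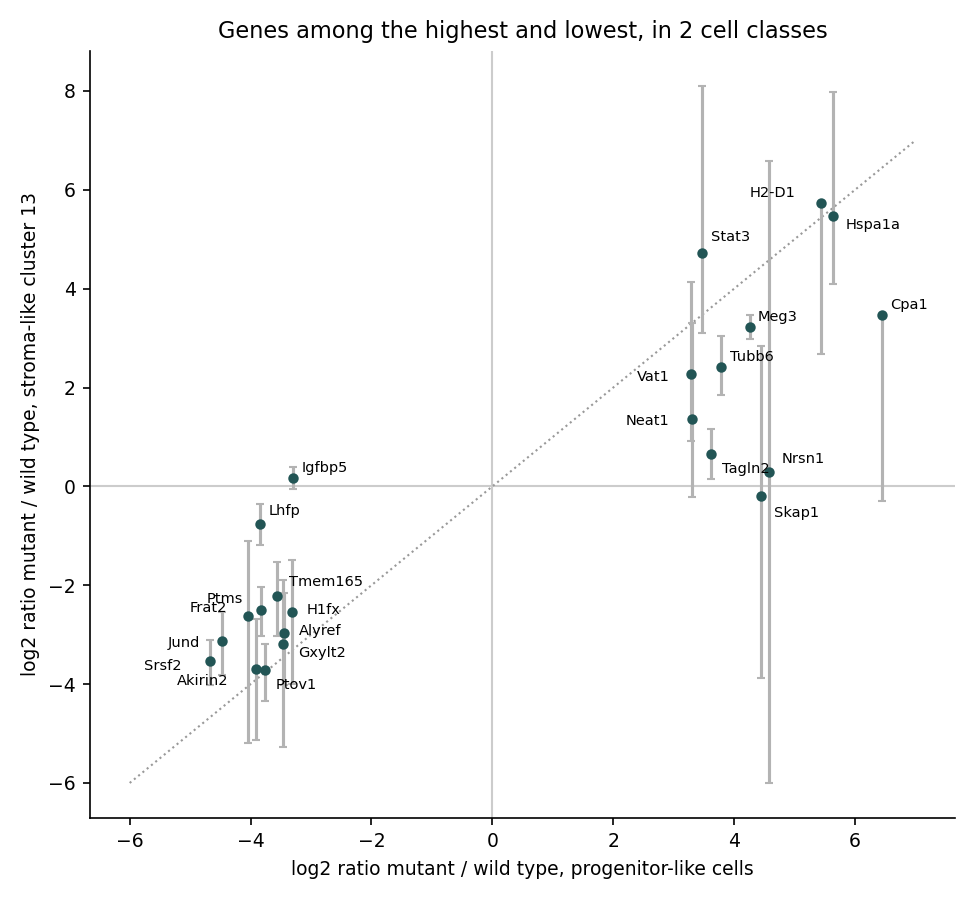
Log2 ratio of mutant to wild type in nephron progenitor-like cells (x axis) and in the stroma-like cluster 13 (y axis) for genes among the 12 highest and for the 12 lowest, with exact 95% counting intervals on the y axis and a dotted line of equal ratios. A bar without an upper end belongs to a gene with 0 wild-type counts in cluster 13, and Igfbp5 (0.16) and Lhfp (-0.75) lie apart from the other low genes.

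Srsf2 lies on chromosome 11 at 116849901 to 116853094 (minus strand), where Mettl23 and Mfsd11 overlap it on the other strand, and Jund on chromosome 8 at 70698949 to 70700616 (plus strand), where Gm11175 overlaps it on the other strand. Cpa1 lies on the plus strand of chromosome 6 at 30639218 to 30645363. Hspa1a and H2-D1 both lie in the histocompatibility region of chromosome 17, at 34969190 to 34972156 and 35262730 to 35267499, and Gm20481 overlaps Hspa1a on the other strand. H2-D1 belongs to a family of near-identical genes and shares 39.8% of the 31-base words in the last 400 bases of its transcripts with other genes, so its level is uncertain. Whether both libraries carry the same haplotype of this region was not tested, which adds to the uncertainty of H2-D1 and H2-K1. For Meg3 this share is 11.6%. The median log2 ratio over 3159 genes with at least 50 CPM in either library was 0.11, and ratios are to be read relative to that shift.

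Regulators of nephron progenitor identity went both ways in the mutant, with 13 of 22 measured members lower and 9 higher (median log2 ratio -0.52, interval -1.12 to 0.18, percentile 0.07). Relative to stroma-like cells, whose wild-type members held progenitor transcripts, the median turned to 2.01, and relative to cluster 13 to 1.44. Uncx stood at 82.5 and 16.49 CPM (-2.32), the transcriptional cofactor gene Cited1 at 128 and 41.9 CPM (-1.61), Trps1 at 29.5 and 11.4 CPM (-1.38) and Hoxd11 at 147 and 64.3 CPM (-1.19). Without the members that also served as class markers, the median was -0.58. Six2, the gene of the sort, was detected in 17.1% of thinned wild-type and 12% of thinned mutant progenitor-like cells, against 5.60% of wild-type and 0 of 453 mutant stroma-like cells, and in 33.6% and 35.7% of progenitor-like cells without thinning. Cited1 was detected in 19.8% and 7.10% of thinned cells, in 32.4% and 16.47% without thinning, and in 2.40% and 0.442% of thinned stroma-like cells. Median depths of the stroma-like cells were 5033 and 5999 UMIs.

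Genes of early nephron differentiation and Wnt signalling went both ways in mutant nephron progenitor-like cells, with 7 of 11 members lower (median -0.73, interval -1.88 to 0.73, percentile 0.49). The Notch ligand gene Jag1 (-2.21), Wnt4, which drives the mesenchyme to epithelium transition (-1.88), and Notch2 (-1.70) were lower. Pax8, an early nephron transcription factor gene, was higher, at 68.7 and 155 CPM (1.18). These values depended on which mutant cells were called progenitor-like. With mutant cells assigned to wild-type clusters, which lack endothelium-, ureteric epithelium- and proximal tubule-like classes, the median was 0.02. Wnt4 then stood at 0.02 and Jag1 at -0.31. Without class markers 3 members were higher and 3 lower (median -0.27, interval -1.70 to 0.73, percentile 13.4).

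Of the Hox genes, 19 of 24 were lower (median -0.57, interval -1.06 to -0.08, percentile 0.02), among them Hoxc8 (-1.57) and Hoxa10 (-1.45). Linker histones and high-mobility group proteins were lower in 17 of 20 members (median -0.68, interval -0.90 to -0.18, percentile 0), with Hmgn2 at 1214 and 443 CPM (-1.45) beside H1fx. Hoxa10 and Hmgn2 were also lower in stroma-like cells, at -1.11 and -1.24. Glycolysis genes were higher in 14 of 16 members (median 0.66, interval 0.44 to 1.05, percentile 99.9), led by the phosphofructokinase gene Pfkp (3.74), while Pgk1 was lower (-1.87). Oxidative phosphorylation genes had a median of 0.08 with 16 of 23 higher, and Atp5a1 stood at 0.73. Relative to the ratio in stroma-like cells, glycolysis genes had a median of 0.71 (interval -0.08 to 1.14, 9 of 13 higher) and Hox genes one of 0.55 (0.07 to 1.42, 15 of 20 higher), although Hoxc8 (-0.94, interval -1.50 to -0.38) and Hoxa10 (-0.33, -0.60 to -0.06) remained lower. Linker histones and high-mobility group proteins had a median of -0.19 on that scale, with 10 of 17 lower (interval -0.27 to 0.53, percentile 0.53). This scale sets wild-type cells that held progenitor transcripts against mutant cells mainly of another cluster. Relative to cluster 13 alone the medians were 0.44 for glycolysis (-0.03 to 0.85), 0.13 for Hox genes (-0.44 to 0.59) and -0.26 for linker histones and high-mobility group proteins (-0.53 to 0.047).

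Replication genes of S phase were higher in 28 of 41 members (median 0.40, interval 0.07 to 0.48, percentile 98.6), although Ccne2 (-1.87) and Usp1 (-1.71) were lower. Relative to stroma-like cells the median was 0.066 (interval -0.17 to 0.38), with 20 of 34 higher (percentile 31.3), and relative to cluster 13 it was 0.21 (0.015 to 0.51), with 23 of 32 higher (percentile 91.5). Genes of G2/M phase were evenly split, with 24 of 50 higher (median -0.01), Tubb4b at 1.41 and Lbr at -1.56, but the median was -0.58 without doublet removal, and relative to stroma-like cells 42 of 47 were lower (median -0.73, percentile 0), as were 42 of 45 relative to cluster 13 (-0.81). The targets of p53 were lower in 9 of 13 members (median -0.42, interval -0.64 to 0.33, percentile 2.66). Relative to stroma-like cells 6 of 10 were lower (median -0.59, interval -1.84 to 0.92, percentile 0.18). Relative to cluster 13 the median was 0.0008 (interval -0.28 to 0.50), with 5 of 9 higher (percentile 27.0). Cdkn1a, the p53-induced cell cycle inhibitor gene, stood at 70.1 and 25.2 CPM (-1.48), and at -1.11 without cluster 14, in which 161 wild-type cells held it at 1533 CPM. The list median without that cluster was -0.28. Ei24 stood at -0.74, Plk2 at 0.97 and Zmat3 at 0.89. The 3 measured CDK inhibitors had a median of -0.02, with Cdkn2d at 1.10, and relative to stroma-like cells all 3 were lower (median -1.48, percentile 0.07), but relative to cluster 13 the median was 0.02, with 2 of 3 higher. Apoptosis genes had a median of -0.02, with 7 of 15 higher, and the proapoptotic gene Bid stood at 6.46 and 29.9 CPM (2.21).

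Neuronal genes were higher in 4 of 5 measured members (median 1.01, interval -3.13 to 6.78, percentile 89.0). Stmn2 stood at 0.105 and 12.9 CPM (6.78), Elavl4 at 1.60 and Uchl1 at 1.01, whereas Syt4 was lower (-3.13). Stmn2 was high in mutant stroma-like cells too (5.76). Germline genes had 0 measured members of 17. Imprinted genes had a median of -0.12, with 5 of 12 higher and Meg3 the highest, and relative to stroma-like cells one of -0.89 with 10 of 12 lower (percentile 0), but relative to cluster 13 one of -0.20 with 6 of 12 lower (interval -1.21 to 0.43). Stromal and extracellular matrix genes had a median of -1.14, with 4 of 6 lower (interval -2.93 to 1.98) and Mgp at -2.93. Muscle and skeletal lineage genes had a median of 0.16 and the tendon transcription factor gene Scx stood at -3.09. Dissociation stress genes were higher in 13 of 18 members (median 0.43, interval -0.52 to 1.15, percentile 96.8), with Hspa1a and Jund at opposite ends, and 17 of 18 were lower relative to stroma-like cells and 16 of 18 relative to cluster 13.

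Within the HDAC family 5 of 8 members were higher (median 0.19, interval -2.32 to 1.19, percentile 64.8), with Hdac8 at 5.07 and 11.6 CPM (1.19) and Hdac4 at 0.40. Subunits of the NuRD, Sin3 and CoREST complexes had a median of 0.02, with 10 of 19 higher, and the Sin3 subunit gene Suds3 stood at 83.1 and 17.0 CPM (-2.29), as it did in stroma-like cells (-2.09). Of the genes that show the sex of the embryos, Xist was lower (-2.96) and Eif2s3y (1.52) and Ddx3y (0.39) were higher. Xist was detected in 66.2% of wild-type and 16.6% of mutant progenitor-like cells. By these 3 genes the libraries differed in their mix of sexes. The Y-linked genes Kdm5d (6.53 and 7.73 CPM) and Uty (8.70 and 8.91 CPM) were close in the 2 libraries, so not all genes go with such a difference.

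**Figure D4:**
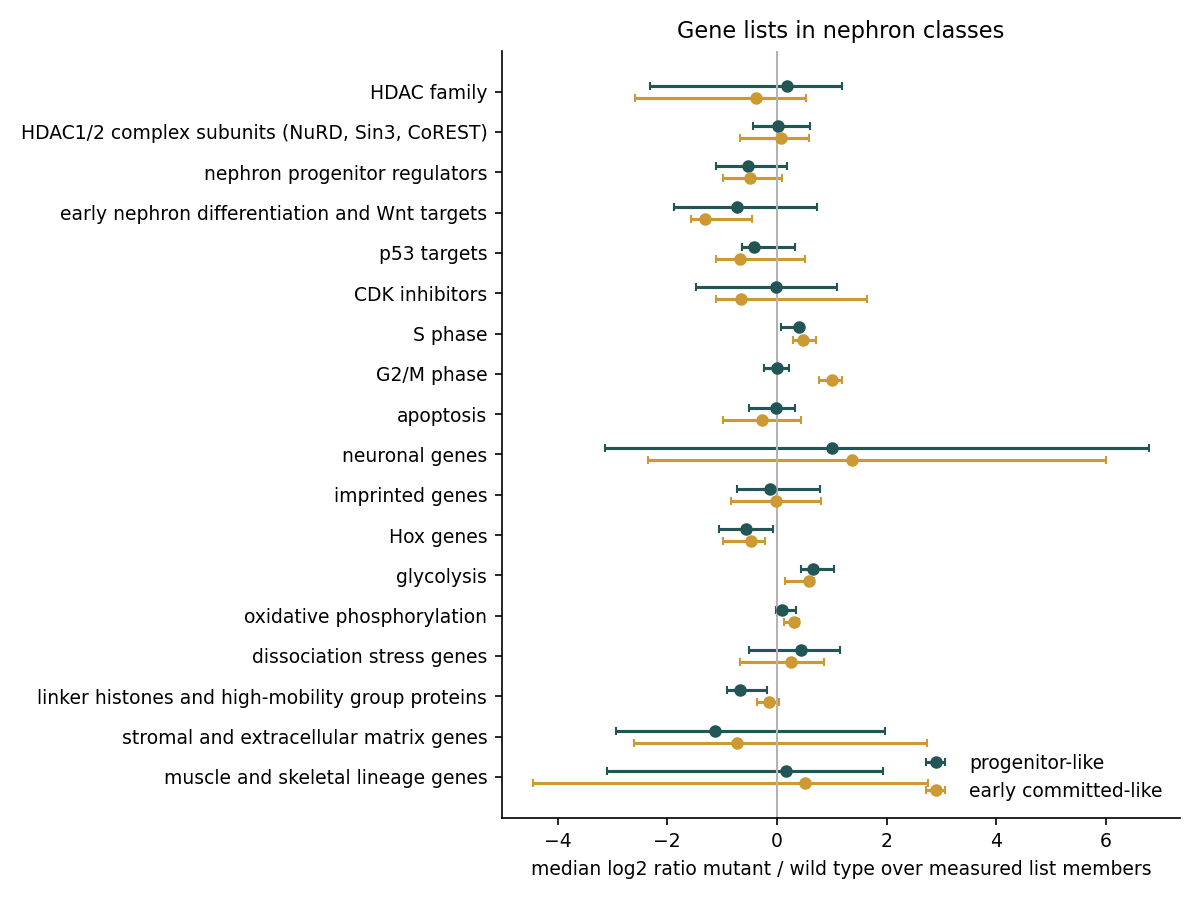
Median log2 ratio of mutant to wild type over the measured members of each gene list with at least 3 measured members in both classes, the genes of sex left out, with order-statistic 95% intervals (the range of the members in short lists), in progenitor-like cells (dark green) and early committed nephron-like cells (ochre). G2/M genes have a median of -0.01 in progenitor-like and 1.00 in early committed cells.

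In early committed nephron-like cells, Fgf8, Emx2 and Notch1 were lower in the mutant library, and Mki67 and Ndc80, genes of dividing cells, were higher. Of the early differentiation and Wnt list, 13 of 17 members were lower (median -1.31, interval -1.56 to -0.46, percentile 0). Fgf8, a growth factor gene needed for nephron formation, stood at 107 and 10.1 CPM (-3.40), Emx2 at 33.3 and 9.05 CPM (-1.88), Notch1 at -1.75 and Notch2 at -1.70. Without the genes that served as class markers 5 of 8 were lower (median -0.66, interval -1.75 to 0.59, percentile 2.02). Genes of G2/M phase were higher in 44 of 52 members (median 1.00, interval 0.76 to 1.18, percentile 100), with Tubb4b at 2.14, Ndc80 at 2.13, Mki67 at 1.95 and Tacc3 at 1.84. Relative to the ratio in progenitor-like cells, 51 of 52 G2/M genes were higher (median 0.93), but relative to stroma-like cells only 27 of 48 were (median 0.15, interval -0.04 to 0.36), and relative to cluster 13 25 of 45 (0.10, -0.06 to 0.31). These values compare clusters 8 and 10 of wild type with clusters 3 and 7 of the mutant, which need not be the same stage.

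The genes with the lowest ratio in early committed nephron-like cells were Jund (-4.38), Srsf2 (-4.36), Id4, an inhibitor of differentiation gene (-3.80), and Akirin2 (-3.78). The highest were H2-D1 at 2.01 and 136 CPM (6.03), Pfkp at 1.29 and 58.0 CPM (5.41), Lypd1 (4.69) and H2-K1 (4.03), which like H2-D1 shares sequence with its relatives (27.4% of words). Of the other lists, nephron progenitor regulators (median -0.50, interval -0.99 to 0.09, 14 of 21 lower) and p53 targets (-0.67, -1.11 to 0.52, 8 of 13 lower) went both ways, and Hox genes (-0.47, 20 of 25 lower) were mostly lower. Relative to stroma-like cells regulators had a median of 2.49 (13 of 16 higher) and Hox genes one of 0.72 (16 of 20 higher), and relative to cluster 13 the medians were 1.35 (14 of 16 higher) and 0.37 (-0.32 to 0.63, 11 of 21 higher). The p53 targets had a median of -0.35 relative to stroma-like cells (-2.02 to 1.00, 6 of 10 lower). Relative to cluster 13 their median was 0.086 (-1.14 to 1.17, 6 of 9 higher). S phase (0.47, 33 of 41 higher), glycolysis (0.58, 14 of 16 higher) and oxidative phosphorylation (0.31, 19 of 23 higher) were mostly higher. Relative to stroma-like cells the median was 0.19 for S phase (-0.10 to 0.56, 22 of 34 higher), 0.54 for glycolysis (-0.37 to 0.90, 9 of 13 higher) and 0.28 for oxidative phosphorylation (19 of 23 higher). Relative to cluster 13 it was 0.32 (0.04 to 0.66), 0.23 (-0.21 to 0.60) and 0.20 (-0.05 to 0.42).

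Stroma-like cells served as cells of another lineage, and their comparison follows the rule for other classes. Of the 127 wild-type cells 126 came from cluster 13, and mutant cells came mainly from cluster 12, which differs in makeup. The lowest genes were Rspo1 (-5.30), Eya1 (-4.71), Six3 (-4.34) and Srsf2 (-4.21). Of these, Eya1 is a nephron progenitor marker gene, and Rspo1 was among the 10 leading genes of the progenitor-like cluster 0 of wild type. The highest were the extracellular matrix gene Fbln2, Clec3b, the renin gene Ren1 and Htra3, each with 0 wild-type counts in 706785 UMIs. Against the limit of 4.24 CPM that 3 counts give, their mutant levels were 63.3-fold, 52.4-fold, 32.5-fold and 24.8-fold higher, without the counting error of the mutant sums. The lower ends of the exact intervals of the log2 ratio were 5.68 for Fbln2 and 5.41 for Clec3b.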

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

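All tests reported in this part were chosen only after the results were seen.

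Haemoglobin transcripts, which no comparison used, stood at 331.73 CPM in the mutant library and at 0.196 CPM in the wild-type library. Of these mutant counts 97.7% were in 5 cells, without which the level was 7.55 CPM. Transcripts of 4 Y-linked genes together stood at 112.629 CPM in the mutant library against 67.97 CPM in the wild-type library, in which 66.2% of cells held Xist against 10.3% of mutant cells. The Y-linked sum differed through Eif2s3y (48.0 against 16.7 CPM) and Ddx3y (49.2 against 36.1 CPM), whereas Kdm5d (7.30 against 6.70 CPM) and Uty (8.18 against 8.44 CPM) were alike.

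Hspa1a was high in mutant nephron progenitor-like cells (log2 ratio 5.64), but not evenly over the cells of the library. Among female cells its log2 ratio to wild type was 0.94 (interval -0.17 to 1.86), on 12 mutant and 39 wild-type counts. This argues against an effect of genotype as large as 5.64 in every mutant cell. A smaller effect in every mutant cell stays open. Male mutant cells exceeded female mutant cells by 5.51 (4.76 to 6.52), against 1.05 (0.21 to 1.83) in wild type, so the sex of the cells alone does not account for the difference either. Jun, another gene of the dissociation stress list, also differed between male and female mutant cells (1.85, against 0.42 in wild type), and embryos or dissociations pooled within the mutant library may differ in stress. That explanation cannot be told apart from an effect of genotype limited to some embryos, because no label ties a cell to its embryo.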

How the results depend on the processing

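The settings limited to male or to female cells, without haemoglobin-rich cells, relative to stroma-like cells or to cluster 13, without class markers and without cluster 14 were chosen after seeing the data, and all others in advance. No paired analysis was possible because there was 1 library per genotype. Hdac1 in progenitor-like cells stayed between -2.40 and -2.24 under every setting but that relative to cluster 13 (-2.04). Hdac2 reversed relative to stroma-like cells (0.54) and to cluster 13 (0.30, interval -0.07 to 0.66). It stood at -0.52 with the stricter cell filter, -0.54 with median ratio scaling, -0.37 with equal weight per cell and -0.38 in female cells, and over all cells at -0.58, -0.63, -0.46 and -0.39 under these, -0.58 without doublet removal and -0.59 in male cells. Hdac1 over all cells was -2.21 in female cells. The wild-type progenitor-like share was 77.8% and 65.9% at Leiden resolutions 0.5 and 2, 86.9% with genes centred by library, 83.9% with the stricter filter, 86.8% without doublet removal and 81.1% with assignment to wild-type clusters, and the mutant share 49.4% with centring and 77.4% with assignment. Relative to stroma-like cells the medians were 2.01 for progenitor regulators, 0.066 for S phase and -0.73 for G2/M phase, relative to cluster 13 they were 1.44, 0.21 and -0.81, and wild-type stroma-like cells held progenitor transcripts such as Eya1. S phase stood at 0.51 at resolution 2 and 0.52 without doublet removal, and G2/M phase at -0.58 without doublet removal and -0.27 in female cells. Among the single genes Wnt4 reversed, to 0.020 with assignment to wild-type clusters. For these differences the cause was not tested, except that assignment by construction places mutant cells by wild-type profiles. Of the single genes and shares with a UMI under settings fixed in advance, 500 values stayed within the interval of the main value, 75 moved in the same direction beyond it and 1 reversed, and under added settings 62 stayed and 51 moved. Of the main results, 112 stayed and 18 moved beyond the interval under settings fixed in advance. Under added settings 46 stayed, 11 moved beyond it and 2 reversed. Depth limits low genes: 1 count in wild-type stroma-like cells is worth 1.41 CPM.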

Other observations

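All tests reported in this part, with the comparison of male and female cells, were chosen only after the results were seen.

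Male and female cells of the mutant library were unlike in Id genes and in class. Among mutant nephron progenitor-like cells, Id1, an inhibitor of differentiation gene, stood at 970 CPM in 588 female cells and at 149 CPM in 1938 male cells (log2 ratio of male to female -2.70, interval -2.78 to -2.63). Id3 stood at 3048 and 815 CPM (-1.90), Id2 at 487 and 147 CPM (-1.73) and Glo1 at 209 and 93.0 CPM (-1.17), whereas Fos was higher in male cells (1.74). In wild-type cells the same ratios were -0.04 for Id1, 0.10 for Id3, 0.16 for Id2, 0.10 for Glo1 and 0.25 for Fos. Hdac1 stood at 15.1 and 15.7 CPM in female and male mutant cells. Cells with Xist made up 16.6% of mutant progenitor-like but 2.19% (1.62 to 2.89) of mutant early committed nephron-like cells, against 66.2% and 64.5% in wild type.

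The 12 lowest genes of mutant nephron progenitor-like cells, among them Srsf2, Jund and Akirin2, had a median log2 ratio of -2.80 (order-statistic interval -3.54 to -2.22) in stroma-like cluster 13, which the choice of these genes did not use. Progenitor RNA in the wild-type cells of that cluster is argued against as the whole cause there, since with the wild-type progenitor profile taken off at 51.6%, the highest share that a progenitor marker (Eya1) gave, the median was -2.85 (-3.27 to -1.28), although Frat2 came to -0.57. The low ratios in cluster 13 argue against a loss of Hdac1 and Hdac2 that acts within nephron lineage cells alone as the whole cause for the set. They leave it open for Igfbp5 (0.16, and -0.48 with the progenitor share taken off). It also stays open for Frat2 (-2.62 and -0.57) and Lhfp (-0.75 and -1.28), whose values depend on that step. Less Hdac2 in mutant cells of that cluster (-0.76, with Hdac1 at -0.28) leaves open a loss of Hdac2 that reaches stroma-like cells. All but Lhfp and Igfbp5 also stood under their wild-type progenitor-like level in every named mutant class outside both nephron classes. Among these classes, proximal tubule-like cells are of a nephron segment and so not of another lineage. Srsf2 stood at 83.5 CPM in mutant endothelium-like, 78.4 CPM in ureteric epithelium-like, 83.9 CPM in proximal tubule-like and 67.9 CPM in leukocyte-like cells. Its level in wild-type progenitor-like cells was 1077 CPM. The wild-type library held too few cells of these classes to compare like with like. Removing the trend with the GC content of the 3' end left the median in progenitor-like cells at -3.72, and removing that with transcript length left it at -3.87. Each trend was the median ratio of genes of like GC content or length, and the 12 genes were chosen as the lowest. These 2 values therefore argue only against a shift that most genes of like GC content or length share. Of the 12 genes 0 shared over 10% of their 31-base words with another gene, against 22.2% of all genes. This argues against reads shared with other genes as the whole cause. A difference between the libraries other than genotype may reach many cell types, as the correlation of 0.74 across genes between progenitor-like cells and cluster 13 allows (0.60 with the progenitor share taken off, 0.098 from that share alone), but with 1 library each it cannot be told apart from genotype. These correlations leave out genes under 20 CPM in mutant cells of cluster 13, such as Six2 (3.52 CPM) and Eya1 (7.04 CPM). They therefore cannot show how much the progenitor share adds through such genes.

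Cpa1, Nrsn1 and Skap1 were singled out as high in mutant nephron progenitor-like cells and lower in the named mutant classes outside both nephron classes. Being lower there was part of the choice and is not a separate result. RNA from pancreatic acinar cells is argued against by 13 acinar genes, of which the highest, Cela1, stood at 0.252 CPM, with Cpa1 at 51.4 CPM. The sex mix is argued against by log2 ratios of 4.25 or more within male cells and within female cells. Loss of Hdac1 and Hdac2 in these cells may raise these genes, Cpa1 by 6.45, but this cannot be told apart from other differences between single libraries that affect nephron lineage cells. All 3 were also higher in mutant early committed nephron-like cells, Skap1 at 70.7 against 4.88 CPM, Nrsn1 at 14.2 against 0.430 CPM and Cpa1 at 3.10 against 0.143 CPM, a level of Cpa1 that mutant stroma-like (3.04 CPM) and endothelium-like cells (5.48 CPM) also had and that lay more in cluster 7 (6.47 CPM) than in cluster 3 (1.44 CPM).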
